A study of Mus musculus with 6 samples.

How the data were processed

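RNA from 3 wild-type and 3 Sox15 knockout samples of mouse embryonic stem cells was sequenced after removal of ribosomal RNA, per the labels' protocols. Salmon 0.12.0, DESeq2 and the mm10 build are named in the submitters' processing notes. The annotation and the step from transcripts to genes are not given in the sources used here. The authors deposited 1 gene table with 6 columns of values. Those values were not used here, because the 6 column names matched no sample's labels, and 6 columns were left out for this reason.

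Only the header and the gene identifiers of the table were read for the results. Each column name was sought as a whole word, ignoring case, in the title, description, source name and characteristics of each sample. Gene identifiers were matched, without version numbers, to the GENCODE M21 gene names. The test of knockout against wild-type cells, the gene lists and the alternatives that had been fixed before the data were examined were not run. While the table was first inspected, its first rows, column totals and the correlations between columns were seen, and none of these was used to assign a column.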

Results

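The series measured gene expression by RNA sequencing in mouse embryonic stem cells, the pluripotent cells derived from the early embryo. Its 6 samples comprised 3 wild-type samples and 3 samples from cells lacking Sox15, an HMG-box transcription factor of the Sox family. The cells were grown with serum and LIF, the cytokine that maintains self-renewal. Ribosomal RNA was removed from total RNA before library preparation.

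The design implied 1 comparison, of Sox15 knockout with wild-type cells. It was not made here. The gene table held 6 columns of values, named s1 to s6, and 0 of these names occurred in the labels of any sample. No column was therefore assigned to a genotype. Column order and the values themselves, including the level of Sox15, were not used in place of a label. No expression level, fold change, test or sequencing depth is reported, and no gene is described as higher or lower in either genotype.

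The rows of the table were 46679 mouse Ensembl gene identifiers, of which 0 were repeated. In the GENCODE M21 gene names, 46201 of these identifiers, or 98.98%, were found. These counts describe the gene catalogue of the table and do not compare expression between the genotypes. Whether genes had been left out of the table by their expression was not checked.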

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

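No paired analysis was possible because the columns of the table carry no replicate number that the labels tie to a sample. The other tests, filters and normalizations fixed beforehand were not run. Some of these steps can be computed without the genotypes, but the comparison they served needs the genotype of every column. The matching rules described here were chosen after the header had been seen. With a column name accepted anywhere inside the labels, 0 columns matched exactly 1 sample, as with whole words. With only the number in the column name compared with the replicate number in the titles, 1 column matched exactly 1 sample, 2 columns matched 2 samples each and 3 columns matched none. The single match arose because the title of 1 wild-type sample has no replicate number. That sample was numbered 3 in accession order, as a name only, and with this number 0 columns matched exactly 1 sample and 3 columns matched 2 samples each. Neither rule was used to assign a column.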
